A study of Gallus gallus with 5 samples.

How the data were processed

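The series holds RNA-seq libraries of chicken DT40 cells, a B-cell lymphoma line, in which the gene of CAP-H, a subunit of the condensin I complex, was altered. Per the labels, 3 libraries came from cells without doxycycline (labelled CAP-H on, replicates 1, 2 and 3) and 2 from cells given 100 ng/ml doxycycline (labelled CAP-H off, replicates 1 and 3), with a treatment time of 36 h. Total RNA was extracted and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

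The deposited count files give whole-number counts per RefSeq transcript identifier with a chromosome, a start and an end on the chicken build galGal4, and 17036 rows each. The submitters' processing notes name TopHat2 2.0.8b, Bowtie, FastQC and edgeR 3.2.3, with no roles. The read counter, the strand setting and any filter are not given in the sources used here. The column names in the headers of the deposited count files stand 1 place off the columns, and the contents of the columns were taken from their values. The smallest count in the deposited files was 1 and none was 0, so a feature with no reads was taken to hold 1. Values of 4, 6, 8 or 10 occurred 3851 times and values of 3, 5, 7 or 9 occurred 3106 times, a ratio of 1.24, so the 2 mates of a read pair may have been counted separately. The authors' deposited comparison table gives log2 fold changes, log2 mean CPM, p-values and adjusted p-values per transcript, per the file headers, in the layout edgeR writes for a likelihood ratio test. Its likelihood ratio column is a score, the test statistic of the authors' comparison per the file headers, and was not used here. The direction of the deposited table is not stated there, and its largest adjusted p-value is 0.05, so it lists called transcripts.

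Before testing, rows that were the same measurement were reduced to 1. A total of 7 identifiers stood at more than 1 interval and 665 intervals stood under more than 1 identifier, with equal counts in each case, which left 16143 features. In 0 of 121 nested pairs with at least 500 counts in the inner feature did the outer feature hold fewer counts than the inner one. A read was therefore taken to count for each feature whose span it overlaps, and counts of the 2095 features (13.0%) that overlap another cannot be assigned to either. No strand was given, so antisense reads are not separated. Gene symbols came from a RefSeq table of the assembly GRCg7b, matched on the accession without its version. Of the 17036 rows, 8905 (52.3%, holding 62.7% of the counts) received a symbol and 818 matched with their version. The protein accession also gave a symbol in 8451 of these rows and differed in 0. Coordinates printed are those of the files, on galGal4, and 0 rows matched NCAPH, the gene of CAP-H.

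Total counts were 22533003, 14890956 and 12311777 in the libraries labelled CAP-H on (replicates 1, 2 and 3) and 13501033 and 12199522 in those labelled CAP-H off (replicates 1 and 3). Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit, glmQLFTest) without covariates, after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05 over 10079 features. TMM factors were 1.07, 1.04 and 1.04 in the libraries labelled CAP-H on and 0.928 and 0.927 in those labelled CAP-H off. CPM values, from edgeR's cpm function with these factors, are given as mean ± SD, and the SE of a log2 fold change is its size over the square root of the F statistic. Tested on simulated counts for the 10079 features with 200 of them changed, the test recovered 82% of changes of 1 and 62% of changes of 0.5 on the log2 scale, and 8.86% of its calls were false. Far fewer features changed there than were called in the data, so these rates need not hold for the data.

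Before the data were examined, 31 gene lists were fixed, along with the rule for named genes. These are the measured condensin subunits, the 12 largest rises and 12 largest falls among changed genes with a symbol, a mean of at least 5 CPM and groups that do not overlap, and up to 4 members of lowest p per list (2, with values only, where none passed). Features named outside the rule are said to be so. Some genes that the rule names are not reported here. The 29 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The mitochondrially encoded list had 0 features, and the list of erythroid cell and thrombocyte markers had too few tested members. The 29 chromosomes with at least 20 tested features were tested in the same way. Neighbouring features were compared by Spearman's correlation of their log2 fold changes, with 10000 permutations within chromosomes. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, edgeR's exact test, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. GC content was not analysed here, since no genome sequence was used.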

Results

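RNA was sequenced from DT40 cells, a chicken B-cell lymphoma line, carrying a conditional alteration of CAP-H, the kleisin subunit of condensin I, the complex that compacts chromosomes. The 3 libraries labelled CAP-H on came from cells without doxycycline, and the 2 labelled CAP-H off from cells given 100 ng/ml doxycycline, at 36 h. Total counts ranged from 12199522 to 22533003 per library. The comparison asks how RNA levels differ once CAP-H has been switched off. Log2 fold changes are those of the libraries labelled CAP-H off minus those labelled CAP-H on, and "rose" and "fell" refer to that direction. Levels are CPM as mean ± SD with n = 3 for the libraries labelled CAP-H on and n = 2 for those labelled CAP-H off, and adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

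Log2 CPM correlated at 0.993 to 0.994 between libraries labelled CAP-H on, at 0.989 between the 2 labelled CAP-H off and at 0.971 between the groups. The first principal component held 70.2% of the variance and separated the groups, and the second held 12.6% and separated the 2 libraries labelled CAP-H off. Differences between replicates exceeded sampling noise by 2.59 to 3.89 times, a ratio that counting the 2 mates of a pair separately would raise. The 10 features with the most counts took 6.46% to 6.63% of the counts in the libraries labelled CAP-H on and 11.3% and 12.1% in those labelled CAP-H off.

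The targeted gene could not be read directly, because 0 rows of the files matched NCAPH by accession, so the labels were not checked by it. A predicted RNA without a gene symbol, XR_140315.1 (galGal4 chromosome 22, 2937123 to 2946787), lies next to TACR1 in the files. It was singled out after its values were seen. In the reference table NCAPH is the next protein-coding gene after TACR1, but the following gene is MAT2L2 there and MXD1 in the files, so the RNA is not identified as NCAPH. Its counts were 406, 279 and 208 in the libraries labelled CAP-H on (replicates 1, 2 and 3) and 185556 and 175268 in those labelled CAP-H off (replicates 1 and 3). The level rose from 18.1 ± 0.94 to 16011 ± 514 CPM, a log2 fold change of 9.79 (SE 0.04, adjusted p = 6.4e-25), which is 886-fold. If this RNA came from the NCAPH locus, its direction would go against the labels, and every direction below rests on the labels as given.

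Among the 6 measured condensin subunits, NCAPD2, the condensin I subunit CAP-D2, rose from 393 ± 18.6 to 857 ± 18.3 CPM (log2 fold change 1.12, SE 0.05, adjusted p = 2.1e-10). NCAPD2 (chromosome 1, 76401650 to 76425373) lies close to MRPL51 (76399982 to 76401536) and GAPDH (76433607 to 76437499). Those genes rose as well, by 1.04 and 0.73, and whether these rises are separate was not tested. The condensin II subunit NCAPH2 rose by 0.22 (SE 0.06, adjusted p = 0.011) and NCAPD3 fell by 0.21 on the log2 scale (SE 0.06, adjusted p = 0.0089). The core ATPases SMC2 and SMC4, shared by both complexes, had log2 fold changes of 0.02 (adjusted p = 0.80) and -0.08 (adjusted p = 0.31), and NCAPG2 had -0.08 (adjusted p = 0.26). Adjusted over the list alone, 2 subunits rose and 1 fell, and camera gave adjusted p = 0.78 for the list. With scaling by library size alone SMC2 turned to -0.16 (adjusted p = 0.016), SMC4 and NCAPG2 passed as lower at -0.26 each, and NCAPH2 lost its call at 0.03 (adjusted p = 0.70). NCAPH2 also lost its call without CAP-H off replicate 3 (0.16, adjusted p = 0.18), and NCAPD3 lost its call by edgeR's exact test (-0.21, adjusted p = 0.063). Under a likelihood ratio test with the replicate number as a block both lost their calls (NCAPD3 -0.22, adjusted p = 0.19; NCAPH2 0.22, adjusted p = 0.052). SMC4 spans a microRNA gene, whose reads are counted with it.

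**Figure D1:**
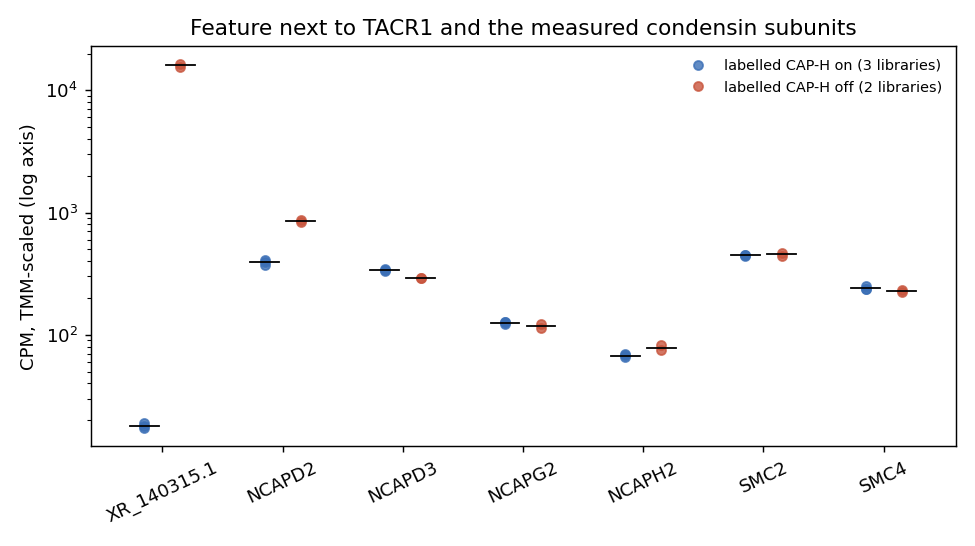
Level in CPM (log axis) of XR_140315.1, the RNA next to TACR1, and of the 6 measured condensin subunits, 1 point per library (blue, labelled CAP-H on; red, labelled CAP-H off) with bars at the group means. XR_140315.1 lies near 18.1 CPM in the 3 libraries labelled CAP-H on and near 16011 CPM in the 2 labelled CAP-H off, and NCAPD2 at 393 and 857 CPM.

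Of the 10079 features tested, 4668 (46.3%) changed, with 2281 higher and 2387 lower in the libraries labelled CAP-H off. At least 2-fold changes were found in 352 features that rose and 271 that fell. The largest rises among genes with a symbol include THRB, the thyroid hormone receptor beta, which went from 3.04 ± 0.70 to 18.4 ± 1.83 CPM (log2 fold change 2.62, SE 0.19, adjusted p = 2.6e-08; chromosome 2, 37812352 to 37892115). ACAP3 rose by 2.63 (SE 0.23), the linker histone gene HIST1H101 by 1.87 (SE 0.11), L3HYPDH, a hydroxyproline dehydratase, by 1.84 (SE 0.10), and DUSP23, a phosphatase, by 1.75 (SE 0.16). Further rises were those of ASIC2, an acid-sensing ion channel (1.67, SE 0.15), CISD3 (1.67, SE 0.16), CNKSR2 (1.65, SE 0.09), HIST1H2A4 (1.57, SE 0.05) and RPS21 (1.55, SE 0.06).

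The deepest falls among genes with a symbol were those of GSTA3, a glutathione transferase, at -2.53 (SE 0.32; 7.89 ± 1.83 to 1.35 ± 0.59 CPM), KCNMB1, a potassium channel subunit, at -2.44 (SE 0.24), PRR5 at -2.25 (SE 0.22) and SLC7A11, the cystine transporter, at -2.25 (SE 0.07). SLC7A11 (chromosome 4, 28379183 to 28433902) went from 156 ± 8.60 to 32.9 ± 3.38 CPM (adjusted p = 3.3e-12). CHAC1, which degrades glutathione, fell by 1.99 on the log2 scale (SE 0.08), and SIAH2, a ubiquitin ligase, changed by -1.88 (SE 0.08). CAPN6 (-2.09, SE 0.26), LITAF (-1.98, SE 0.21), KCNIP1 (-1.97, SE 0.13), TF, the transferrin gene (-1.90, SE 0.24), and SLC9A5 (-1.89, SE 0.23) fell too. KCNMB1 lies inside the span of KCNIP1, so reads of this pair are not separated.

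By the same rule KLHDC1 (3.82, SE 0.69, adjusted p = 0.00029) and KLHDC2 (2.84, SE 0.49, adjusted p = 0.00021) had the 2 largest rises, but 1 library decides both. Without CAP-H off replicate 1, KLHDC1 came to 0.15 (adjusted p = 0.30) and KLHDC2 to 0.52 (adjusted p = 3.6e-06), and without CAP-H off replicate 3 they came to 4.76 and 3.70. Both lie in a run of 7 features on chromosome 5 (57481365 to 57585710), from LRR1 to NEMF, each at 1101 CPM or more in CAP-H off replicate 1. In CAP-H off replicate 3 KLHDC2 stood at 135 CPM, against a mean of 94.4 in the libraries labelled CAP-H on. In CAP-H off replicate 1 LRR1 stood at 1110 CPM against 23.1 on average in the other 4 libraries, DNAAF2 at 1101 against 16.0, POLE2 at 1214 against 138 and NEMF at 1200 against 122. LRR1, DNAAF2, POLE2 and NEMF were named after their values were seen.

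**Figure D2:**
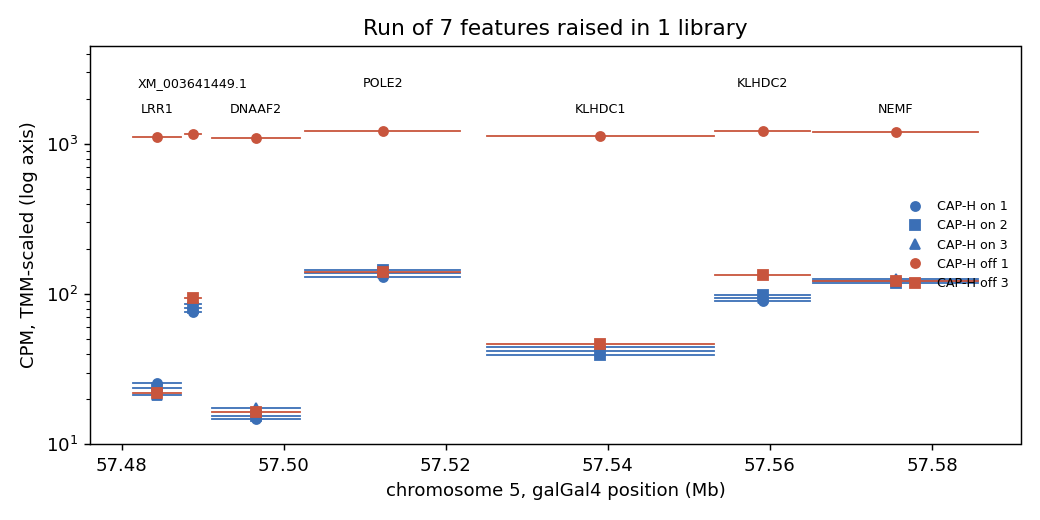
Level in CPM (log axis) of the 7 features of the run on chromosome 5 by galGal4 position in Mb, with lines over each feature's span and points at its middle, 1 marker per library. CAP-H off replicate 1 lies at 1101 to 1218 CPM in each feature, and the other 4 libraries lie between about 16.0 CPM (DNAAF2) and 138 CPM (POLE2) on average.

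At unadjusted p under 0.05, 5348 features passed, and in 6544 (64.9%) the groups did not overlap, where chance gives 20%. Scaling by library size alone moved the median log2 fold change of all features by -0.18 and changed the split to 1272 higher and 4119 lower (23.6% of the calls higher against 48.9% under TMM), so directions here are relative to the typical feature.

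Genes of the cytosolic ribosome showed the most uniform change. All 43 measured ribosomal protein genes rose (43 adjusted over the list alone), with a median log2 fold change of 0.87, and 42 of them still rose with scaling by library size alone. RPL7 went from 2407 ± 101 to 5103 ± 3.16 CPM (1.08, SE 0.03, adjusted p = 1.4e-12), RPL7A rose by 1.18 (SE 0.04), RPL13 by 1.31 (SE 0.04) and RPL3 by 1.16 (SE 0.04). Camera with the preset correlation gave adjusted p = 3.35e-20, and adjusted p = 0.41 with an estimated correlation. Histone genes rose in 17 of 19 cases (17 adjusted over the list alone, 13 with library size alone), with a median of 0.81 (camera adjusted p = 4.9e-08, and adjusted p = 0.46 with an estimated correlation). The replication-dependent gene HIST1H2A4 went from 884 ± 55.6 to 2627 ± 147 CPM, HIST1H2A4L4 rose by 1.22 (SE 0.04), HIST1H4I by 1.29 (SE 0.06) and H2AFJ by 1.32 (SE 0.06). These genes lie in 1 stretch of chromosome 1, from 47958619 to 48033079, so their rises need not be independent. Random lists matched to the histone genes on expression and genomic span had a median of 0.70 (central 95% from 0.35 to 0.92). Those lists could hold histone genes without a symbol. Histone and ribosomal protein genes have near-identical copies, among which the counting could split reads, so single members are uncertain.

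Of 39 nuclear-encoded genes of oxidative phosphorylation 28 rose, 1 fell and 10 did not pass (31 and 2 adjusted over the list alone), with a median of 0.35. COX7A2, a subunit of cytochrome c oxidase, went from 99.7 ± 5.39 to 191 ± 6.68 CPM (0.94, SE 0.06, adjusted p = 2.0e-09), and the ATP synthase subunit genes ATP5E (0.92, SE 0.06) and ATP5I (0.94, SE 0.06) and the complex III gene UQCR11 (0.92, SE 0.07) rose alike. Camera gave adjusted p = 5.4e-07, and adjusted p = 0.52 with an estimated correlation. Of 46 mitochondrial ribosome and translation genes 14 rose, 2 fell and 30 did not pass (14 and 2 adjusted over the list alone), led by MRPL51 (1.04, SE 0.05), MRPL57 (0.71, SE 0.07), MRPL17 (0.81, SE 0.08) and MRPL10 (0.51, SE 0.06). For this list camera gave adjusted p = 0.0057, and adjusted p = 0.71 with an estimated correlation. Without CAP-H on replicate 3, 22 mitochondrial ribosome genes rose, 1 fell without either library labelled CAP-H off, and with library size alone 11 rose and 12 fell. With library size alone 20 genes of oxidative phosphorylation rose and 3 fell, and the count that fell was 2 without CAP-H on replicate 1.

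Cholesterol and fatty acid synthesis genes rose in 13 of 20 cases, fell in 3 and did not pass in 4 (13 and 3 adjusted over the list alone), with a median of 0.39. HMGCS1 (408 ± 9.70 to 771 ± 35.5 CPM; 0.92, SE 0.05, adjusted p = 1.8e-09) and MSMO1 (0.94, SE 0.07) rose, and ELOVL5 (-0.60, SE 0.05), ACLY (-0.63, SE 0.06) and FASN (-0.35, SE 0.04) fell. ACLY and FASN were named after their values were seen. Camera gave adjusted p = 0.0057 for this list, and adjusted p = 0.52 with an estimated correlation. Kinetochore genes rose in 7 of 18 cases and fell in 1, with 10 not passing (6 and 1 adjusted over the list alone). OIP5 (0.58, SE 0.08), CENPP (0.52, SE 0.10) and CENPM (0.52, SE 0.11) rose, and KNL1 fell (-0.31, SE 0.06). OIP5 (chromosome 5, 23856171 to 23859084) lies close to NUSAP1 of the mitosis list (23859403 to 23873314), which rose by 0.51. Whether these rises are separate was not tested. CENPP and KNL1 overlap other features, and with library size alone 4 kinetochore genes rose and 1 fell. The kinetochore call (camera adjusted p = 0.020, and adjusted p = 0.39 with an estimated correlation) was lost without CAP-H off replicate 1 (adjusted p = 0.053).

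Targets of the integrated stress response, a stress programme that acts through ATF4, fell in 20 of 24 cases, rose in 2 and did not pass in 2. Adjusted over the list alone 20 fell and 2 rose, and the median of the list was -0.75. After SLC7A11 and CHAC1, the strongest calls were those of CEBPG, a transcription factor (means of 82.8 and 26.1 CPM; -1.66, SE 0.07, adjusted p = 5.3e-11), and PSPH, of serine synthesis (-1.31, SE 0.06). ATF4 itself went from 538 ± 19.6 to 300.3 ± 2.40 CPM (-0.84, SE 0.06). The 2 members that rose were CTH (0.58, SE 0.07) and EIF4EBP1 (0.34, SE 0.07). Camera gave adjusted p = 4.9e-08, and adjusted p = 0.39 with an estimated correlation. With library size alone 22 fell and 2 rose. PSPH overlaps an unnamed feature. ATF4, CTH and EIF4EBP1 were named after their values were seen.

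**Figure D3:**
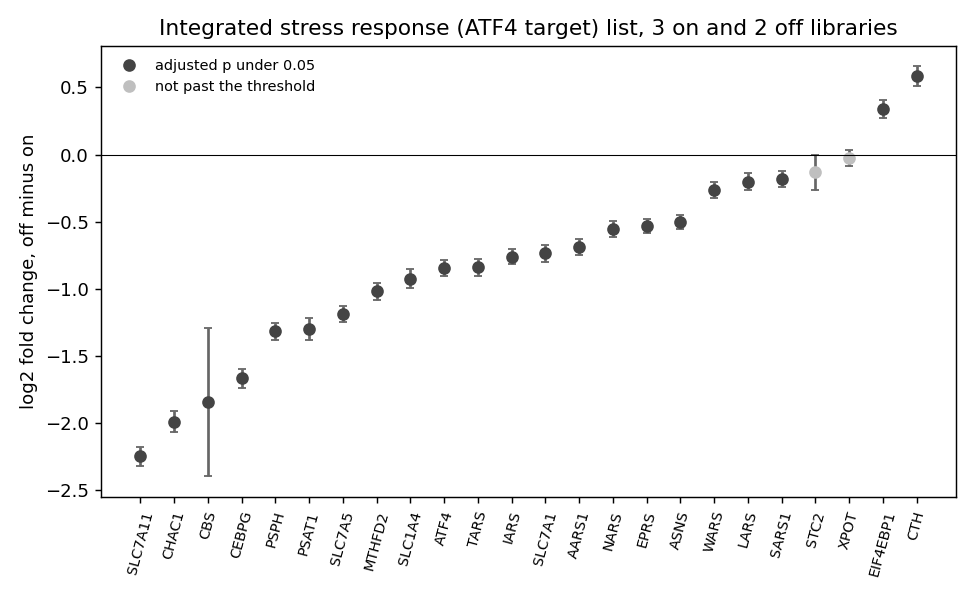
Log2 fold change (libraries labelled CAP-H off minus on) of the 24 measured members of the integrated stress response list, with bars of 1 SE; dark points passed the adjusted p threshold of 0.05. The values run from -2.25 (SLC7A11) to 0.58 (CTH), and 20 members fell.

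Genes of endoplasmic reticulum chaperones and the unfolded protein response fell in 11 of 17 cases, rose in 2 and did not pass in 4 (11 and 2 adjusted over the list alone). HSP90B1 went from 759.7 ± 19.2 to 482 ± 8.59 CPM (-0.66, SE 0.05, adjusted p = 4.4e-08), and SEL1L (-0.69, SE 0.06), HSPA5, the chaperone BiP (-0.52, SE 0.06), and CANX (-0.42, SE 0.05) fell. Camera gave adjusted p = 0.028, which became 0.064 without CAP-H on replicate 3, and adjusted p = 0.70 with an estimated correlation. Of these genes 13 fell and 1 rose with library size alone.

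B-cell identity and receptor signalling genes fell in 22 of 39 cases, rose in 4 and did not pass in 13 (23 and 4 adjusted over the list alone), with a median of -0.35. IKZF1, the lymphoid transcription factor Ikaros, fell from 209.8 ± 8.05 to 77.7 ± 1.78 CPM (-1.43, SE 0.06, adjusted p = 7.8e-11). TNFRSF13B, the receptor TACI (-1.30, SE 0.11), the signalling adaptor gene PIK3AP1 (-0.65, SE 0.06) and LOC396098 (-0.64, SE 0.07) fell as well. Camera gave adjusted p = 0.0013, and adjusted p = 0.39 with an estimated correlation; with library size alone 27 fell and 2 rose. The 9 measured macrophage and granulocyte markers included 4 that fell, namely MMP9 (20.9 ± 2.67 to 5.80 ± 0.27 CPM; -1.84, SE 0.17), MPEG1 (-1.51, SE 0.15), CTSS (-1.08, SE 0.16) and CYBB (-0.52, SE 0.14), and 5 that did not pass (4 fell adjusted over the list alone). That call (camera adjusted p = 0.026, and adjusted p = 0.39 with an estimated correlation) was lost without CAP-H on replicate 3 (adjusted p = 0.076), where 1 marker rose, and without CAP-H off replicate 3 (adjusted p = 0.20), and with library size alone 6 markers fell.

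Chromatin modifier and remodeller genes fell in 17 of 33 cases, rose in 2 and did not pass in 14 (18 and 2 adjusted over the list alone). The histone demethylase genes KDM3A (135.5 ± 5.32 to 92.6 ± 1.89 CPM; -0.55, SE 0.05, adjusted p = 7.4e-07) and KDM5A (-0.58, SE 0.06), the SWI/SNF subunit gene SMARCB1 (-0.48, SE 0.05) and the deacetylase gene HDAC9 (-0.52, SE 0.06) fell. Camera gave adjusted p = 0.0032, and adjusted p = 0.39 with an estimated correlation, and 1 member rose without CAP-H on replicate 1, CAP-H on replicate 2 or CAP-H off replicate 1. Library size alone gave 26 falls and 1 rise of chromatin genes, and 13 falls and 1 rise of nuclear pore genes. Nuclear pore genes fell in 11 of 15 cases, rose in 2 and did not pass in 2 (11 and 2 adjusted over the list alone), with NUP210 going from 1371 ± 46.2 to 933 ± 24.4 CPM (-0.55, SE 0.04, adjusted p = 5.1e-08), NUP62 changing by -0.47 (SE 0.06), TPR by -0.34 (SE 0.06) and NUP50 by -0.38 (SE 0.06). For the pore list camera gave adjusted p = 0.020, and adjusted p = 0.39 with an estimated correlation; NUP62 and TPR overlap other features.

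**Figure D4:**
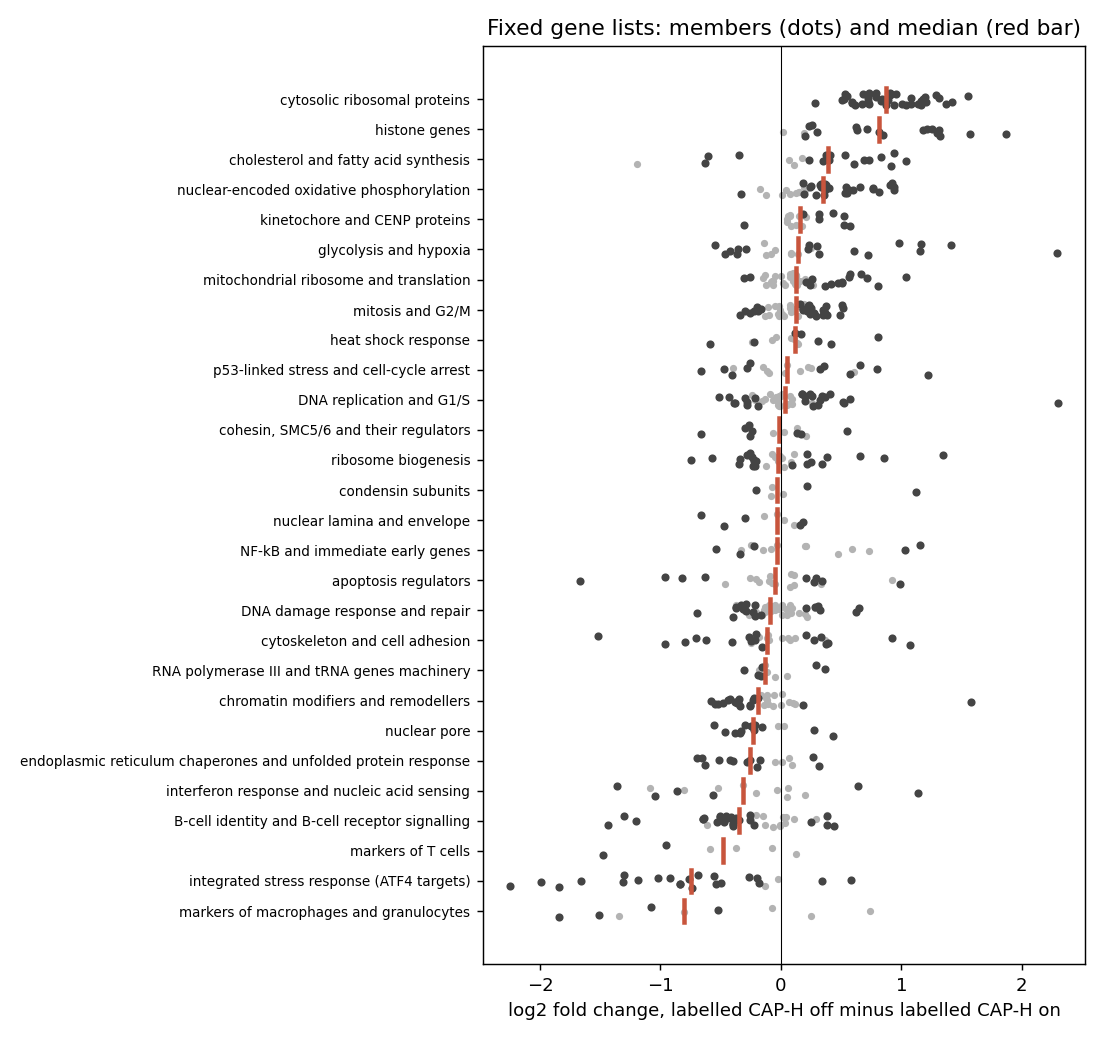
Log2 fold change (libraries labelled CAP-H off minus on) of each measured member of the fixed gene lists that hold at least 5 members, dark where the adjusted p was under 0.05 and grey where it was not, with a red bar at the list median. Ribosomal protein genes (median 0.87) and histone genes (0.81) lie at the top, and integrated stress response targets (-0.75) and macrophage markers (-0.80) at the bottom.

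In total camera with the preset correlation passed 12 of the 29 lists, 6 of them higher and 6 lower in the libraries labelled CAP-H off. None of the 12 calls (0) held with an estimated correlation. Only the ribosomal protein, histone, oxidative phosphorylation and stress response lists were compared with random lists matched on expression and genomic span. The rotation test fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, passed 21 lists, 9 higher and 12 lower.

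Mitosis and G2/M genes rose in 20 of 46 cases and fell in 7 (20 and 7 adjusted over the list alone; camera adjusted p = 0.082, and 0.041 without CAP-H off replicate 3), with 9 rises and 18 falls under library size alone. NUSAP1, a spindle protein gene (0.51, SE 0.06), CDC25A (0.37, SE 0.05), the kinase genes AURKB (0.52, SE 0.08) and NEK2 (0.38, SE 0.06) rose, and the count that fell was 4 without CAP-H on replicate 2. DNA replication and G1/S genes rose in 16 of 47 cases and fell in 9 (16 and 11 adjusted over the list alone; camera adjusted p = 0.64), with GMNN (0.52, SE 0.06), TK1 (0.57, SE 0.08) and PCNA (0.41, SE 0.06) rising and POLE, the catalytic subunit of DNA polymerase epsilon, falling (-0.52, SE 0.06). The largest of these rises, that of POLE2 (2.30, SE 0.48), comes from the chromosome 5 run in CAP-H off replicate 1. Without CAP-H off replicate 1, 10 replication genes rose, and with library size alone 7 rose and 22 fell. Of 12 genes of cohesin, SMC5/6 and their regulators, 5 fell and 3 rose (5 and 5 adjusted over the list alone; camera adjusted p = 0.73), led by SMC5 (-0.67, SE 0.07), SMC3 (-0.30, SE 0.06), PDS5B (-0.25, SE 0.06) and NSMCE4A (0.55, SE 0.08). SMC5, like CDC25A, overlaps another feature. The count that rose was 1 without CAP-H on replicate 2, CAP-H off replicate 1 or CAP-H off replicate 3, 1 (with 6 falling) with library size alone and 5 with upper quartile scaling.

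DNA damage genes fell in 12 of 44 cases and rose in 6 (12 and 6 adjusted over the list alone; camera adjusted p = 0.38), with FANCD2 (-0.70, SE 0.08), ERCC3 (-0.31, SE 0.05) and PRKDC (-0.37, SE 0.07) falling and FANCG rising (0.65, SE 0.09). Of 21 genes of p53-linked stress 6 rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.73), among them GADD45A (0.58, SE 0.07), AEN (0.66, SE 0.10), CCNG1 (0.36, SE 0.06) and BTG1 (-0.66, SE 0.06). Apoptosis regulators rose in 5 and fell in 4 of 23 cases (5 and 4 adjusted over the list alone; camera adjusted p = 0.88). BCL2L1 went from 86.7 ± 2.42 to 172 ± 18.4 CPM (0.99, SE 0.06, adjusted p = 3.8e-09), and BAK1 (-1.67, SE 0.21) and APAF1 (-0.96, SE 0.16) fell. Nuclear lamina genes fell in 3 and rose in 2 of 9 cases (3 and 2 adjusted over the list alone; camera adjusted p = 0.64), with LMNB2 (-0.66, SE 0.07), LEMD2 (-0.48, SE 0.07) and LEMD3 (-0.30, SE 0.07) falling. None of the 2 lamina rises (0) was left without CAP-H on replicate 1, CAP-H on replicate 2 or CAP-H off replicate 1, and 1 was left without CAP-H off replicate 3. With library size alone 29 DNA damage genes fell and 2 rose, 9 apoptosis genes fell and 2 rose, 9 p53-linked genes fell and 5 rose, and 6 lamina genes fell and 0 rose.

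Glycolysis and hypoxia genes rose in 11 of 25 cases and fell in 6 (12 and 6 adjusted over the list alone; camera adjusted p = 0.28), and with library size alone 6 rose and 11 fell. The enzyme genes ENO1 (3897 ± 175 to 8714 ± 194 CPM; 1.16, SE 0.03, adjusted p = 4.4e-13), LDHA (0.98, SE 0.04), GAPDH (0.73, SE 0.04) and PGAM1 (0.61, SE 0.04) rose. Cytoskeleton and adhesion genes fell in 11 and rose in 7 of 28 cases (11 and 7 adjusted over the list alone; camera adjusted p = 0.39), and with library size alone 17 fell and 5 rose. ACTB went from 1618 ± 82.5 to 565 ± 10.4 CPM (-1.52, SE 0.05, adjusted p = 3.3e-12), MYH9 (-0.96, SE 0.04) and TLN1 (-0.79, SE 0.06) fell, and TMSB4X, an actin-binding peptide gene, rose (0.92, SE 0.06). ACTB and PGAM1 overlap other features. Ribosome biogenesis genes fell in 12 and rose in 9 of 31 cases (12 and 9 adjusted over the list alone; camera adjusted p = 0.73), and with library size alone 20 fell and 5 rose. DKC1, of snoRNA particles, rose from 1131 ± 13.7 to 2869 ± 61.4 CPM (1.34, SE 0.03, adjusted p = 3.7e-13), TAF1D (0.86, SE 0.06) and NOP16 (0.66, SE 0.07) rose, and NCL, nucleolin, fell (-0.75, SE 0.04), with a snoRNA inside its span. The median of that list was -0.02 and its mean 0.01, and camera called it lower and fry higher, without passing. The condensin list (median -0.03, mean 0.17) and the NF-kB list (median -0.04, mean 0.16) were likewise called higher by camera, without passing, while their medians were below 0.

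The remaining lists did not pass by camera. Heat shock genes rose in 5 and fell in 2 of 14 cases (6 and 2 adjusted over the list alone; adjusted p = 0.44), including HSPA8 (0.42, SE 0.03), HSPA2 (0.81, SE 0.11) and HSPA4 (-0.59, SE 0.06), with 3 rising without CAP-H off replicate 1, and 2 rising and 6 falling with library size alone. Interferon and nucleic acid sensing genes fell in 4 and rose in 2 of 15 cases (4 and 2 adjusted over the list alone; adjusted p = 0.39), including TLR21 (-1.36, SE 0.15), TLR7 (-1.05, SE 0.15) and IFI35 (1.14, SE 0.24), with 1 rising without CAP-H on replicate 1 or without either library labelled CAP-H off, and 6 falling and 1 rising with library size alone. NF-kB and immediate early genes fell in 3 and rose in 2 of 15 cases (3 and 2 adjusted over the list alone; adjusted p = 0.84), with REL (-0.54, SE 0.07) and MYC (-0.23, SE 0.05) falling and JUN rising (1.03, SE 0.14), and 1 rising without CAP-H off replicate 3. With library size alone 6 NF-kB genes fell and 2 rose, and MYC lost its call under the likelihood ratio test with the replicate block (-0.25, adjusted p = 0.15). RNA polymerase III machinery genes fell in 4 and rose in 2 of 11 cases (4 and 2 adjusted over the list alone; adjusted p = 0.61), led by LARP7 (-0.30, SE 0.07), which overlaps 6 other features, among them MIR302A. Of the RNA polymerase III genes 0 rose without CAP-H off replicate 1 and 1 rose without CAP-H on replicate 1, CAP-H on replicate 2 or CAP-H off replicate 3, while 2 fell without CAP-H on replicate 2 and 1 fell without CAP-H off replicate 3. With library size alone 7 of them fell and 0 rose, and with upper quartile scaling 1 fell and 2 rose. Of 6 T cell markers, 2 fell (2 adjusted over the list alone; adjusted p = 0.25), CD5 (-0.95, SE 0.09) and CD8BP (-1.48, SE 0.45). CD8BP stood at 2.08 CPM in the libraries labelled CAP-H on and was not called without CAP-H off replicate 1 (-0.92, adjusted p = 0.20), where 1 marker rose, or with the replicate block (-1.48, adjusted p = 0.053), and it came to -2.31 without CAP-H off replicate 3. Of the T cell markers 3 fell and 0 rose with library size alone. CD5 overlaps VPS37C, and HSPA4 overlaps an unnamed feature. Of 3 fibroblast and epithelium markers, 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.83), with FN1 at 0.42 ± 0.34 and 0.89 ± 0.19 CPM.

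Chromosomes were compared because condensin shapes whole chromosomes. By camera 0 of 29 chromosomes passed, 1 had an unadjusted p under 0.05, and fry passed 8. Chromosome 17 was that one, with 79 features that rose, 36 that fell and a median of 0.15 (camera adjusted p = 0.32). On chromosome 22, which carries XR_140315.1, 27 features rose and 17 fell (camera adjusted p = 0.98).

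Neighbouring features changed together more than permuted ones. Across 10049 adjacent pairs, the Spearman correlation of the log2 fold changes was 0.164 (two-sided permutation p = 1e-04, the smallest that 10000 permutations can give), where the largest permuted value was 0.044. This is a correlation across genes, which are not independent replicates. The difference between 2 libraries of 1 group gave 0.032 (CAP-H on replicates 2 and 3), 0.031 (CAP-H on replicates 1 and 3) and 0.085 (CAP-H off replicates 1 and 3). Without overlapping features the value between groups was 0.139, against 0.020 (CAP-H on replicates 2 and 3) and 0.076 (CAP-H off replicates 1 and 3). Differences of single libraries are noisier than the group contrast, so they are no like background. Like spans of neighbours and alignments running over adjacent features were not tested as sources.

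The authors' deposited table lists 3798 transcripts, 1303 with a positive and 2495 with a negative log2 fold change. Of the transcripts in the authors' deposited table, 3690 were tested here, all with the sign found here, and 3522 passed the threshold. Log2 fold changes here and in the authors' deposited table correlated at 0.995 across transcripts, with a median difference of 0.10 (here minus deposited). That table comes from the same series and lists only called transcripts, so shared signs were likely in advance and are no independent support. XR_140315.1 has 9.73 and SLC7A11 has -2.37 in the authors' deposited table.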

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

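The alternatives that set the smallest value to 0, kept each row as its own feature, left out overlapping features or used a likelihood ratio test with the replicate block were chosen only after the files were seen. The count of changed features (4668) kept within 1.5 times under each of 18 alternatives, from 3839 to 5391. Leaving out 1 library in turn gave 3839 to 4448, where a group left with 1 library is assumed to vary like the other. Scaling by library size alone (5391) shifted the median log2 fold change of all features by -0.18, and 3661 of its calls were shared. Gene list calls moved from 12 to 0 with an estimated correlation and to 21 with fry, which tests each list by itself. They were 10 to 12 with 1 library labelled CAP-H on left out. The estimated correlations were 0.53 for ribosomal protein, 0.46 for histone and 0.32 for oxidative phosphorylation genes, against the preset 0.01. Those of the kinetochore (-0.026), nuclear pore (-0.0009), chromatin (-0.030) and macrophage (0.0086) lists lay below the preset. A higher correlation thus does not account for the loss of these last calls. With an estimated correlation camera also takes p-values from the residual degrees of freedom, few here, and not from the number of features. From the preset to the estimated correlation, the unadjusted camera p of the nuclear pore list went from 0.0065 to 0.062. The loss of a call thus reflects the few libraries as well as any correlation. Chromosome calls moved from 0 to 8 with fry, with 0 when any 1 library was left out. The correlation of neighbours stayed between 0.143 and 0.165 with 1 library left out, and fell to 0.059 for features 2 places apart. Of 3690 deposited transcripts tested, 3510 passed by the exact test against 3522.

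Of 136 named genes 122 kept direction and call under each alternative run. SMC2 reversed under library size only, to -0.16, as that scaling lowers all values. For the shared replicate numbers 1 and 3, deviations from the group means correlated between the groups at -0.01 and -0.03. The deviations of the 2 libraries labelled CAP-H off mirror each other, so these values are not independent. They do not decide whether the replicate numbers pair the libraries. With the replicate block 3856 features changed, 12 lists and 0 chromosomes passed, the neighbour correlation was 0.161 and 3316 deposited transcripts passed. The result for NCAPH gave no value, as no row matched it, and the pseudocount and value filter alternatives had no use for counts. In the simulation 62% of changes of 0.5 were recovered, but only 200 features changed there, against 4668 called in the data. The adjusted threshold therefore allows a higher unadjusted p in the data, and the simulated rates need not hold for these calls. Small changes may still be missed.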

Other observations

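The tests of the RNA next to TACR1 and of the run on chromosome 5 were chosen only after these results were seen, and the further gene groups here were chosen after the files were seen but before their values were read. Translation initiation and elongation factor genes rose in 19 of 41 cases and fell in 9, with a median of 0.15 and camera adjusted p = 0.0594 over 4 such groups. EIF3E (0.74, SE 0.06), EIF3M (0.64, SE 0.06) and the helicase gene EIF4A2 (0.51, SE 0.04) rose, while EIF4G2 fell from 3069 ± 67.4 to 1982 ± 21.3 CPM (-0.63, SE 0.03, adjusted p = 2.6e-10 by edgeR's quasi-likelihood test). Splicing factor genes fell in 17 of 38 cases and rose in 7 (median -0.11, camera adjusted p = 0.0594), among them PRPF8 (-0.69, SE 0.06), HNRNPM (-0.60, SE 0.06), HNRNPA2B1 (-0.52, SE 0.05) and SRSF6 (-0.54, SE 0.06).

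Proteasome genes rose in 9 and fell in 4 of 28 cases (camera adjusted p = 0.537), with PSMG4 at 1.14 (SE 0.08) and PSMD2 at -0.69 (SE 0.06). Of 7 subunits of the cytosolic chaperonin 3 rose and 1 fell (camera adjusted p = 0.883), with TCP1 at 0.24 (SE 0.05) and CCT2 at -0.24 (SE 0.06).

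The RNA next to TACR1 was higher by 9.79 on the log2 scale in the libraries labelled CAP-H off. A single wrongly labelled library is argued against by the lowest of these, 821 times the highest library labelled CAP-H on, and alignments spanning several features by the 4 flanking features, which moved by at most 0.0116% of the CPM gained. A candidate explanation is that the CAP-H state of the groups is the reverse of the labels, since NCAPH is the protein-coding gene after TACR1 in the reference table. This cannot be told apart from a correct labelling, because 0 rows matched NCAPH by accession and the RNA could be another transcript that rises with doxycycline. An effect of doxycycline itself was not tested, as no library of cells with intact CAP-H and doxycycline was analysed here.

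Runs of neighbouring features were raised in 1 library each. On chromosome 5, from LRR1 to NEMF, CAP-H off replicate 1 gained 1087 ± 12.6 CPM in each of 7 features, a coefficient of variation of 1.16%, and on chromosome 1 (76676056 to 76735288, from LAG3) CAP-H off replicate 3 gained 2.74 CPM in each of 5 features, with 3.35%. More copies of a region would multiply each feature alike, but the largest fold was 7.81 times the smallest on chromosome 5 and 7.71 times on chromosome 1. Equal added counts are what alignments spanning the whole run, counted in each feature, would give, and they may be why KLHDC1, KLHDC2 and POLE2 appear raised.

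Of the lists that camera passed, those of ribosomal protein, histone, oxidative phosphorylation and stress response genes were set against 2 technical explanations. These were a trend of fold change with expression and genomic span (Spearman's rho with span -0.226 over 10079 features) and the scaling of the libraries. The other lists that passed were not set against the trend, which stays open for them. The median of ribosomal protein genes lay 0.487 above that of 10000 matched lists, oxidative phosphorylation 0.268 above and stress response targets at -0.693 from theirs. Each lay outside the central 95%. That range treats members as independent, while the estimated correlations of these lists were 0.53, 0.32 and 0.13, so it is too narrow. The comparison argues against the trend as the whole cause only as far as members vary independently. Histone genes lay 0.109 above, inside that range. Only members with a symbol were kept out of the matched lists, so these could hold unnamed histone genes. The comparison therefore leaves open whether the trend accounts for the histone genes. Under library size alone 97.7% of the called ribosomal protein genes kept call and direction, which argues against scaling as their cause, while the 100% of stress response targets that did so says little, since that scaling lowers all values and most of these had fallen. For histone genes 76.5% and for oxidative phosphorylation 72.4% kept theirs, which leaves scaling open in part. For the ribosomal protein genes and stress response targets a response to the CAP-H state or to doxycycline remains a hypothesis. The design does not separate these 2 from each other, or from a difference in culture or handling between the groups.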
